A study of Mus musculus with 2 samples.

How the data were processed

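Total RNA was taken from the ventricular and subventricular zones of mouse cerebral cortex at embryonic day 15.5 in the C57BL/6J strain, per the labels' protocols. The tissue was dissected from vibratome slices, made into mRNA libraries with Illumina protocols and sequenced. There were 2 libraries, named WT and CE, with 1 library per group. The series is about cortices depleted of Cenpj, and the labels do not spell out CE, so CE was taken as the depleted library because the other one is named WT.

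The authors deposited one table of FPKM values (mapped fragments scaled by transcript length and by the library's total of mapped fragments) with 22553 genes and a column for each library. Bowtie2 2.1.0 and the mm10 build are named in the submitters' processing notes without a role. The program that counted fragments, the program that computed FPKM, the annotation release, any filter and the strandedness of the libraries were not given in the sources used here. FPKM divides the fragments of a gene by its length and by the library total. A library in which a few genes take more of the fragments therefore has lower values for all other genes.

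The fragments behind the values were recovered from the deposited FPKM values, because a whole number of fragments divided by a whole length and a fixed total leaves a recognisable pattern. The total was found from genes with a single transcript, and came to 13255225 fragments in WT and 16842977 in CE, a ratio of 1.27. With these totals, whole counts in both libraries and a whole length were found for 100% of the 15532 genes with a value above 0 in both, within the rounding of the printed values and with lengths up to 60000 bases. The smallest such length was used, so each count is a lower bound and the intervals made from it are at least as wide as those of the true count. The recovered counts added up to at least 11986467 fragments in WT (90.4% of the total) and 15196675 in CE (90.2%). On 497 simulated genes the procedure found counts for 100%, gave the exact counts for 82.7%, was at or below the true count for 100%, and gave counts to 0% of pairs that were not whole. With wrong totals it gave counts to 0% of 500 of the real genes, with lengths up to 12000 bases, a limit that holds 99.7% of the recovered lengths.

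The measure throughout was log2((CE + 1)/(WT + 1)) of FPKM, with a pseudocount of 1, which understates the difference of low genes. Genes with an FPKM of at least 1 in at least 1 library were kept, with 1 row per symbol, which gave 13417 genes. The 40 rows without a gene symbol held 0.147% of the FPKM sum in WT and 0.0641% in CE and were left out. Plain ratios of FPKM are given with exact 95% Clopper-Pearson intervals made from the recovered counts. These intervals cover counting error only, since fragments amplified by PCR are not independent molecules, and they say nothing of differences between embryos. Where WT was listed at 0, the fold was computed against a floor of 3 counts in that library, a one-sided limit that is less strict than the lower end of these intervals.

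With 1 library per group no test between conditions was possible, and no p-value was computed. For 32 gene lists fixed before the data were examined, the median log2 ratio of the members was set against the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list outside the central 95% of those medians is said to stand apart, as a description of these 2 libraries. About 1.6 of 32 lists would lie outside by chance if genes varied independently. On simulated values for 13417 genes, drawn independently, 75% of 40 lists of 20 members with a 2-fold shift were found above the central range. Of 200 unchanged lists, 5.5% lay outside it. Members of a real list may vary together, which the simulation did not include, so these rates may not hold for the 32 lists.

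The genes named were set by a rule fixed before the data were examined: Cenpj, the 12 highest and 12 lowest log2 ratios among genes with an FPKM of at least 5 in a library, Kif2a and the other members of the cilium disassembly list, and up to 4 members of each list with the largest absolute log2 ratio. Predicted genes, clone names and ribosomal pseudogenes were not named. Some genes that the rule names are not reported here. Genes outside that rule are said to have been chosen after their values were seen.

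Gene positions, GC content and length of the longest transcript came from GENCODE M21 on GRCm38, the assembly also called mm10, in which 21822 of the 22553 gene identifiers were found. Shared sequence was measured on the longest annotated transcript of each gene. It is the percentage of its 50-base words, taken every 5 bases, that also occur in the same orientation in transcripts of another gene. Where the expressed transcript is shorter, the percentage may not hold for it. The alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter and a filter at FPKM 5, a 1.5-fold limit, 10 expression bins, and 3 other scalings between libraries. The scalings were the median ratio, one fixed sum for both libraries (TPM) and a trimmed mean of log ratios with 30% of ratios and 5% of levels trimmed. A correction for GC content and length, with 10 bins of each, and a list of ribosomal protein genes with under 10% shared words were added after the data had been seen. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.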

Results

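Transcript levels were measured by RNA sequencing in the germinal zones of the embryonic mouse cortex, the layers beside the ventricle that hold radial glia and intermediate progenitors. One library was named WT and the other CE, the library taken as depleted of Cenpj, both at E15.5. WT rested on 13255225 fragments and CE on 16842977. At least 1 FPKM was reached by 11939 genes in WT and 13082 in CE. The study asked which transcripts differ in cortices depleted of Cenpj. As there was 1 library per group, no difference has a replicate check, and the intervals given are 95% counting intervals.

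Cenpj, which encodes a centriolar protein needed for centriole duplication, was lower in the CE library. Its level was 7.003 FPKM in WT and 2.75 FPKM in CE, a ratio of 0.393 (0.330 to 0.466) from at least 405 and 202 fragments. The log2 ratio was -1.09. Cenpj (ENSMUSG00000064128) lies on the minus strand of chromosome 14 from 56526761 to 56575425 in GRCm38. The values are for the whole gene, and which part was disrupted was not given in the sources used here. A difference of this size was not rare, as 1505 of 13417 genes (11.2%) had a log2 ratio as low or lower. Cenpj lay at percentile 12.9 among 200 genes of like level.

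Kif2a, a kinesin that depolymerises microtubules and takes part in cilium disassembly, was also lower in CE. It stood at 40.4 FPKM in WT and 17.98 in CE, a ratio of 0.445 (0.393 to 0.503), and 1443 genes (10.8%) were as low or lower. Kif2a lies on the minus strand of chromosome 13 from 106958996 to 107022126. Kif2a was the 1 member of 18 in the cilium disassembly list that was at least 2-fold lower. Pifo, which is linked to the primary cilium and its disassembly, was the 1 member at least 2-fold higher, listed at 0 in WT and at 57.1 FPKM in CE, at least 235-fold higher. Its log2 ratio ranked 15 from the top among 13417 genes. The motile cilia and choroid plexus lists, given below, were also higher in CE (medians 2.06 and 4.31). The kinase genes Aurka (20.1 and 20.4 FPKM), Plk1 (18.4 and 14.9) and Nek2 (7.48 and 7.14), and the deacetylase gene Hdac6 (29.1 and 31.0), were within 2-fold. So were Kif2c (18.8 and 20.4), Kif24 (3.23 and 1.87), Nde1 (37.2 and 29.3), Ndel1 (26.4 and 51.4), Nedd9 (10.8 and 12.7), Tchp (10.8 and 7.65) and Cdc20 (35.0 and 35.6), which shares 11.2% of its words and is uncertain. Trp53bp1 (49.1 and 28.2 FPKM), Kdm3a (23.9 and 23.0) and Nek8 (2.43 and 4.81) were within 2-fold too, as was Dynlt1b (51.7 and 47.7), which shares 82.8% of its 50-base words with other genes and is uncertain. The list's median log2 ratio was -0.02, at percentile 17.6 of random lists, and did not stand apart.

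Of the 12 genes with the highest ratios in CE, 6 were in the list of the choroid plexus, the epithelium that secretes cerebrospinal fluid, and of the cortical hem beside it. These 6 were Ttr, Folr1, Kcnj13, Kcne2, Clic6 and Otx2, while Sostdc1 and Calml4 were not in that list. Ttr, which encodes the thyroid hormone carrier transthyretin, stood at 0.309 FPKM in WT and 8529 FPKM in CE, from 5 fragments in WT. It lies on chromosome 18 from 20665280 to 20674321. Sostdc1, a secreted antagonist of BMP and Wnt signalling, stood at 0.215 and 152.5 FPKM, a ratio of 708 (303 to 2182). Folr1, a folate receptor, stood at 0.0900 and 308.9 FPKM, with 1 fragment in WT and a ratio of 3431 (616 to 135560). Of the potassium channel genes, Kcnj13 stood at 126 FPKM in CE, with 3 fragments in WT and a ratio of 214 (72.8 to 1038), and Kcne2 stood at 193. Kcne2, Clic6 (155 FPKM in CE), the transcription factor gene Otx2 (107) and Calml4 (93.9) each had 1 fragment in WT. The others among the 12 highest were Krt18, a keratin gene listed at 0 in WT and at least 64.8-fold higher in CE, Mlf1 (0.406 and 99.2 FPKM), Sulf1 (0.641 and 106) and the linker histone gene Hist1h1e (0.202 and 79.4), which shares 32.1% of its words and is uncertain.

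Among the 12 genes with the lowest ratios in CE was Emx1, a homeobox gene of the dorsal telencephalon. It stood at 60.5 FPKM in WT and 0.951 in CE, 63.6-fold lower (42.9 to 98.6). Pou3f2, a transcription factor gene of upper-layer neurons and their progenitors, stood at 64.2 and 1.55 FPKM, 41.4-fold lower (30.3 to 57.9). Msi1, an RNA-binding protein gene of neural progenitors, stood at 161 and 4.49 FPKM. Lmtk3 (88.8 and 0.678 FPKM) and Cacng7 (88.3 and 0.673) were each 131-fold lower. Slc8a2, a sodium-calcium exchanger gene, was 107-fold lower, and the kinase genes Nuak1 and Brsk1 were 41.9-fold and 44.2-fold lower. Midn (353 and 9.74 FPKM), Rrp1 (154 and 4.29), Taf15 (114 and 3.57) and Agap2 (39.6 and 0.443) made up the rest.

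Of 13417 genes, 3334 (24.8%) were at least 2-fold higher in CE and 1684 (12.6%) at least 2-fold lower. The counting interval lay wholly beyond 2-fold for 2963 and 1569 genes. The median log2 ratio of all genes was 0.33, and the Pearson correlation of log2 values was 0.794 across genes, which are not independent replicates. The split of higher to lower genes depended on the scaling: it was 2554 to 2187 with median-ratio scaling, which moved the median of all genes by -0.23, and 2229 to 2505 with trimmed-mean scaling, which moved it by -0.35. Scaling to TPM moved the median by -0.16 and gave 3196 and 2311 genes. The random lists against which each gene list is set carry the same shift.

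**Figure D1:**
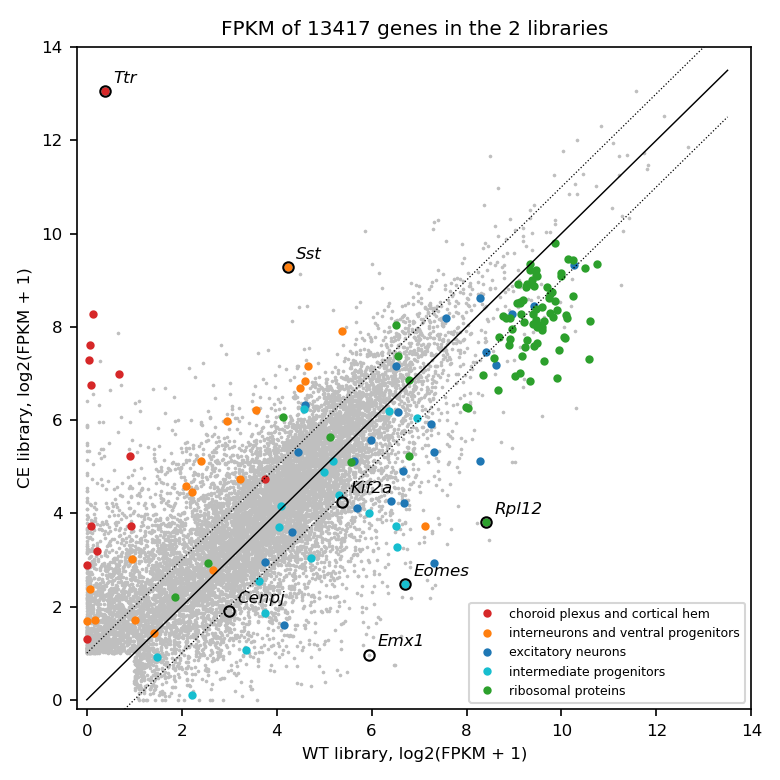
FPKM of 13417 genes in the WT library (x axis) and the CE library (y axis), both as log2(FPKM + 1), with 1 grey point per gene and the members of 5 gene lists in colour. The solid line marks equal values and the dotted lines a 2-fold difference; Ttr lies at 0.309 FPKM in WT and 8529 FPKM in CE, and most ribosomal protein genes lie under the solid line.

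Genes of the choroid plexus, of blood, of macrophages and of the meninges were higher in CE. In the choroid plexus and cortical hem list 12 of 13 members were at least 2-fold higher, with a median log2 ratio of 4.31. In the erythroid list 10 of 11 members were at least 2-fold higher (median 2.87). The embryonic globin gene Hbb-y stood at 21.6 and 562 FPKM, and Alas2, of haem synthesis, at 4.72 and 45.7. The adult globin genes Hbb-bs (359 and 3262 FPKM) and Hba-a2 (159 and 1212) share 65.5% and 87.1% of their words with other genes, so their own levels are uncertain. Of the microglia and macrophage list 15 of 16 members were at least 2-fold higher (median 2.71), among them C1qb of the complement cascade (7.07 and 92.7 FPKM), Fcer1g (1.68 and 35.2), Pf4 (3.60 and 63.4) and Lyz2 (1.13 and 84.3), which shares 15.4% of its words and is uncertain. Of the meningeal fibroblast list 13 of 14 members were (median 2.37), with the collagen gene Col3a1 at 15.48 and 141 FPKM, and the proteoglycan genes Dcn (6.68 and 170), Lum (2.15 and 70.5) and Ogn (1.19 and 71.9). All 4 medians lay at percentile 100 of the random lists. The endothelial list (median 0.39, percentile 66.7, 3 of 15 at least 2-fold higher) and the pericyte list (0.50, percentile 64.2) did not stand apart, nor did they with a filter at FPKM 5, where their medians were 0.69 and 0.87. In the endothelial list Slco1c1 (5.34 and 36.4 FPKM) and Emcn (2.22 and 13.96) were higher and Mfsd2a stood at 21.2 and 10.2, and Ramp2 (14.8 and 57.0) is uncertain for shared sequence. In the pericyte list Vtn (17.0 and 57.4 FPKM), Tagln (2.19 and 7.52) and Acta2 (1.19 and 4.40) were higher and Notch3 (7.26 and 1.76) lower, though not after the correction for GC content and length, which turned its log2 ratio to 0.38.

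Genes of cortical interneurons and their ventral progenitors were higher in CE, with 15 of 19 members at least 2-fold higher and 1 lower (median 2.23, percentile 100). Sst, the neuropeptide gene somatostatin, stood at 17.8 and 620 FPKM, 34.9-fold higher (29.6 to 41.6). Dlx2 and Dlx5, homeobox genes of ventral progenitors, stood at 6.81 and 61.9 FPKM and at 4.34 and 33.6 FPKM. Meis2, also expressed in cortical progenitors, was the member that was lower, at 138 and 12.3 FPKM. Of the Cajal-Retzius list 7 of 10 members were at least 2-fold higher (median 1.89, percentile 99.96), among them Calb2 (5.22 and 49.4 FPKM), Nhlh2 (4.39 and 27.8), Lhx1 (0.785 and 8.43) and Car10 (0.783 and 7.30). Of the motile cilia and multiciliation list 12 of 15 were (median 2.06, percentile 100), beside the choroid plexus list, whose epithelium is multiciliated and whose median was 4.31. Foxj1, the main transcription factor gene of motile cilia, stood at 2.27 and 30.5 FPKM, Tekt1 at 1.76 and 29.9 and Spag6 at 0.937 and 22.3. Rsph1, of the radial spoke, was listed at 0 in WT and at least 87.9-fold higher in CE. Of the interferon response list 12 of 17 were at least 2-fold higher (median 1.44, percentile 99.85), including Ifitm3 (3.004 and 38.8 FPKM) and Bst2 (2.96 and 30.2). Usp18 had 1 fragment in WT and a ratio of 80.3 (14.1 to 3201), and Ifit3 (0.216 and 5.89 FPKM) shares 51.5% of its words and is uncertain.

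**Figure D2:**
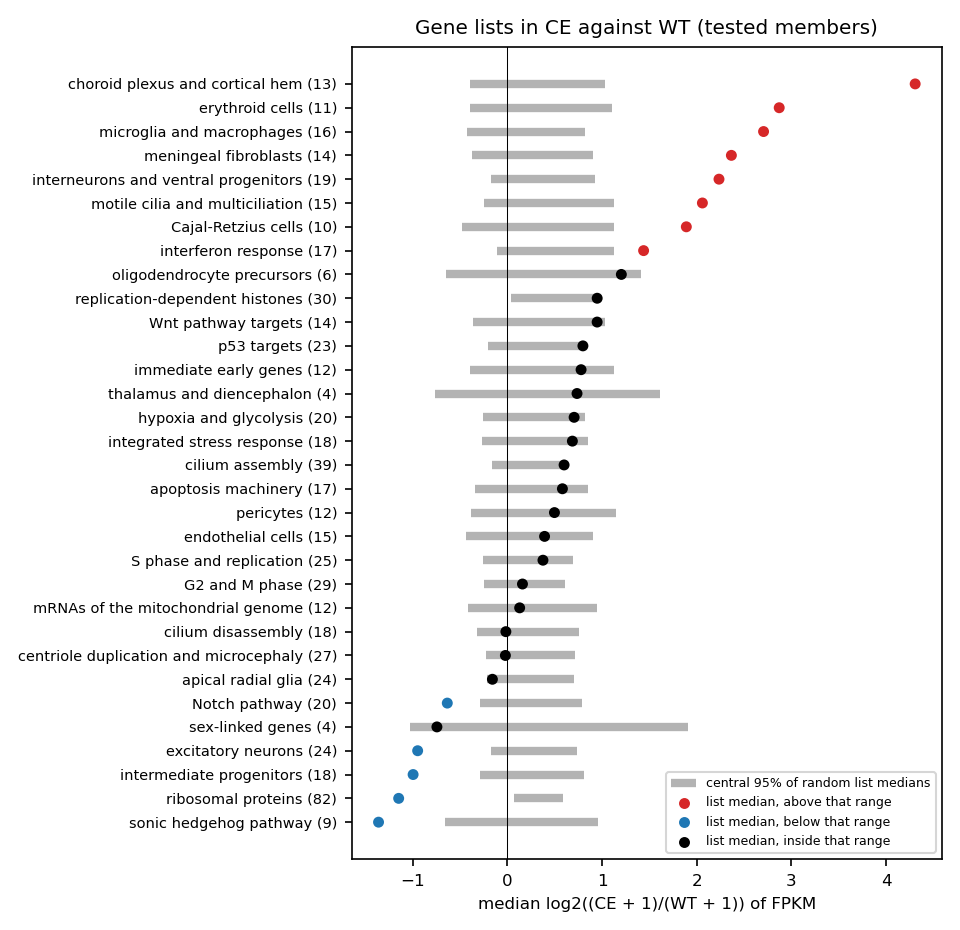
Median log2((CE + 1)/(WT + 1)) of FPKM for each of the 32 gene lists, with the central 95% of the medians of 10000 random lists of the same size and expression. The 8 lists above that range include choroid plexus and cortical hem at 4.31, and the 5 lists under it include ribosomal proteins at -1.15.

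Genes of intermediate progenitors, the dividing daughters of radial glia, were lower in CE, with 9 of 18 members at least 2-fold lower and 1 higher (median -0.996, percentile 0). Eomes, their defining transcription factor gene, stood at 104 and 4.57 FPKM, 22.7-fold lower (19.7 to 26.3). Insm1 stood at 92.3 and 8.73 FPKM, the proneural gene Neurog2 at 90.1 and 12.3, and Kif26b at 9.29 and 1.09. Genes of excitatory neurons were lower as well, with 10 of 24 at least 2-fold lower and 1 higher (median -0.95, percentile 0). Neurod2, a transcription factor gene of these neurons, was 9.26-fold lower (8.63 to 9.94), at 311 and 33.6 FPKM. Bhlhe22 (102 and 17.6 FPKM) and Unc5d (16.8 and 2.02) were lower too. The apical radial glia list lay inside the range (median -0.16, percentile 4.03), with 7 of 24 members at least 2-fold lower and 4 higher, but lay under it (percentile 0.57) after a correction for GC content and gene length. Its members went both ways: Pax6 (55.4 and 11.1 FPKM), Lhx2 (235 and 47.9) and Notch1 (40.6 and 6.22) were lower, and Pla2g7 (1.94 and 29.5) was higher.

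Of the sonic hedgehog list 5 of 9 members were at least 2-fold lower in CE and 0 were higher (median -1.36, percentile 0.09). Cdon, a co-receptor gene, stood at 65.4 and 5.48 FPKM, the transcription factor genes Gli2 and Gli3 at 23.1 and 4.32 FPKM and at 19.0 and 5.39 FPKM, and the ciliary receptor gene Gpr161 at 25.8 and 3.73. Its median was nearer 0 after a correction for GC content and gene length (-0.50, percentile 1.34) and with no filter on FPKM (-0.53). Of the Notch list 6 of 20 were at least 2-fold lower and 3 higher (median -0.63, percentile 0.13). Notch1 and Maml1 (7.42 and 1.43 FPKM) were lower, as was Mfng (25.5 and 7.23), and Dner (10.4 and 74.4) was higher. The Notch list no longer stood apart after that correction, with a median of 0.26 and a percentile of 36.1.

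Genes of ribosomal proteins were lower in CE, with 48 of 82 members at least 2-fold lower and 2 higher (median -1.15, percentile 0). Rps28 stood at 1530 and 158 FPKM, 9.66-fold lower (9.03 to 10.3), and Rpl12 at 341 and 13.1 FPKM. Rps21 stood at 964 and 118 FPKM and Rpl31 at 644 and 113 FPKM. Many of these genes share sequence with pseudogenes. Rpl12, Rps21 and Rpl31 share 16.7%, 19.5% and 33.0% of their words, and are uncertain, while Rps28 shares 5.73%. The longest transcript of Rps28, where this was measured, has 1443 bases against a smallest fitting length of 365, so Rps28 is uncertain too. The 15 members with under 10% shared words had a median of -1.25, and the 67 others a median of -1.12.

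Genes activated by p53 were on the edge of the range, with 8 of 23 at least 2-fold higher in CE and 1 lower (median 0.80, percentile 96.98). The percentile of the list went from 90.96 after the GC and length correction to 99.7 with a pseudocount of 5. The cell cycle inhibitor gene Cdkn1a stood at 4.83 and 50.2 FPKM, 10.4-fold higher (8.21 to 13.3), Ccng1 at 6.17 and 43.4, Perp at 0.516 and 18.7 and Ddit4l at 1.95 and 21.4. In the apoptosis machinery list (median 0.58, percentile 84.9) Casp8 (0.996 and 7.15 FPKM) was higher and Bak1 (13.7 and 1.22) and Xiap (12.8 and 4.12) were lower, and Diablo (39.9 and 102) is uncertain for shared sequence. Genes of centriole duplication and microcephaly did not stand apart (median -0.02, percentile 12.8). Of 27 members, Cdk5rap2 (30.7 and 8.81 FPKM), Cep97 (20.3 and 7.72) and Pcnt (7.67 and 3.10) were among the 4 at least 2-fold lower, and Cetn2 (20.6 and 138) was the 1 at least 2-fold higher. The GC and length correction turned the log2 ratio of Pcnt to 0.33. Genes of cilium assembly also lay at the edge (median 0.60, percentile 97.46), with 14 of 39 at least 2-fold higher and 2 lower. They stood apart under 7 alternatives, but not with a pseudocount of 5 (percentile 94.8) or 10 expression bins (96.9). The medians of the motile cilia list (2.06) and the choroid plexus list (4.31) were higher too. Tctn2 stood at 5.48 and 26.7 FPKM, Ift74 at 10.1 and 33.6 and Bbs5 at 4.52 and 15.03.

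Cell cycle genes were mostly within 2-fold, with 24 of 25 of the S phase list (median 0.38, percentile 73.1) and 26 of 29 of the G2 and M phase list (median 0.16, percentile 42.1). Slbp, the histone mRNA binding protein gene, stood at 30.9 and 94.1 FPKM, Ccne1 at 5.38 and 10.7, Ccne2 at 4.44 and 8.53 and Uhrf1, uncertain with 18.8% of its words shared, at 34.0 and 18.7. The proliferation marker gene Mki67 was lower (28.1 and 8.82 FPKM), Cdk1 higher (26.5 and 65.1), Birc5 stood at 10.5 and 21.5, and Ccnb1 (33.7 and 70.1) shares 42.2% of its words and is uncertain. The median of the G2 and M phase list was below 0 with each of the 3 other scalings. The replication-dependent histone list (median 0.95, percentile 96.4) had 12 of 30 members at least 2-fold higher and 2 lower, the higher ones including Hist1h1b (0.305 and 11.3 FPKM, from 3 fragments in WT, a ratio of 37.0 with an interval of 12.4 to 182). The histone median was 0.30 after the GC and length correction and 0.23 with no filter on FPKM.

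The remaining lists did not stand apart, although the Wnt, hypoxia, oligodendrocyte precursor, mitochondrial and sex-linked lists did after the correction for GC content and length. The Wnt target list (median 0.95, percentile 95.6) had 7 of 14 members at least 2-fold higher, among them Tnfrsf19 (12.49 and 40.2 FPKM), Nkd1 (6.13 and 16.6) and Sp5 (0.359 and 5.97). The hypoxia and glycolysis list (0.70, percentile 93.6) had 8 of 20, with Ankrd37 at 1.14 and 7.49 FPKM and Ldha, which shares 16.9% of its words and is uncertain, at 238 and 874, while Hk2 was lower (8.27 and 1.11). The integrated stress response list (0.69, percentile 91.3) was split between Cebpb (0.301 and 10.1 FPKM) and Sesn2 (1.22 and 8.32), which were higher, and Ddit4 (112 and 6.2) and Atf5 (19.5 and 0.870), which were lower, and its median was 0.02 (percentile 17.9) with a filter at FPKM 5. In the immediate early list (0.78, percentile 86.3) Ier3 stood at 2.13 and 7.56 FPKM, Egr1 at 0.642 and 3.0, Fos at 0.680 and 2.62 and Fosl2 at 6.55 and 1.78. Of the oligodendrocyte precursor list (1.203, percentile 94.3) 4 of 6 were higher, including Olig1 (1.60 and 11.5 FPKM), Olig2 (1.27 and 3.95), Pdgfra (2.22 and 12.3) and Cspg5 (15.4 and 38.8). The thalamus list rested on 4 members (0.74, percentile 68.6), with Lhx9 at 0.457 and 4.07 FPKM, Tcf7l2 at 3.74 and 8.64, Foxp2 at 14.8 and 9.92 and Irx3 at 0.482 and 1.019. Of mRNAs of the mitochondrial genome (0.13, percentile 24.9), whose median was below 0 with each of the 3 other scalings and the GC and length correction, mt-Atp8 (121 and 27.4 FPKM) and mt-Nd6 (389 and 125) were lower. mt-Co3 (3039.5 and 8545 FPKM) and mt-Atp6 (1830 and 5067) were higher, but share 100% and 99.2% of their words with other genes and are uncertain. The Y-linked genes Ddx3y (5.33 and 4.24 FPKM), Uty (3.09 and 2.01), Kdm5d (6.65 and 1.26) and Eif2s3y (8.96 and 3.82) were found in both libraries (median -0.74, percentile 5.75), and no value for Xist was analysed here.

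The ratio between the libraries followed gene length and GC content in these 2 libraries. Among 10 groups of genes ordered by length, the median log2 ratio was 0.78 in the group with the shortest transcripts and -0.60 in that with the longest. Spearman's correlation across genes was -0.37 with length and -0.18 with GC content, over 13340 genes that are not independent replicates. With this trend removed, 2902 genes were at least 2-fold higher and 1125 at least 2-fold lower. Its removal left 83 named gene ratios within their counting interval and moved 75 by more. Another 2, Notch3 and Pcnt, changed sign. The folds of single genes are given without the correction unless stated.

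**Figure D3:**
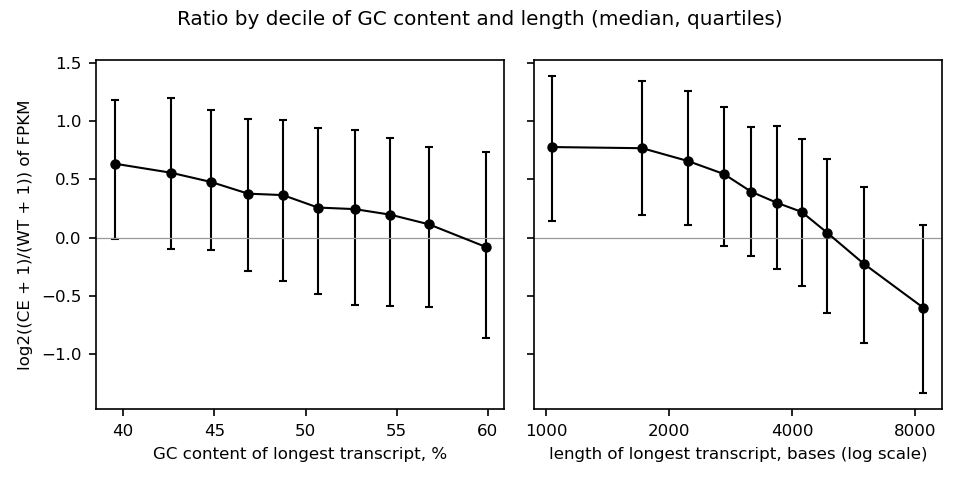
Median log2((CE + 1)/(WT + 1)) of FPKM in 10 groups of genes by GC content (left) and by length of the longest transcript (right, log axis), with bars from the lower to the upper quartile of genes. The medians go from 0.63 to -0.08 with GC content and from 0.78 to -0.60 with length.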

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

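The GC content and length correction and the ribosomal protein list with under 10% shared words were added after the data were seen; all other alternatives were set before. No paired analysis was possible because each group has 1 library, and no library could be left out for the same reason. Of the list results, 266 kept their place inside or outside the central range, 21 moved outside it and 1 moved inside. Of the named gene ratios, 830 stayed within their counting interval, 435 moved by more, and 2 with a log2 ratio of at least 1 in size changed sign. Among the others, 20 with a smaller log2 ratio changed sign. Of the 830, 160 came from using no filter and 149 from the filter at an FPKM of 5. Neither setting alters a gene's own ratio, so these could not move and do not speak for stability. Counts of genes stayed within 1.5 times in 14 cases and moved in 4. The thalamus list had too few members at an FPKM of 5 for a value. Depth limits genes with a few fragments in WT, as their intervals show.

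With a 1.5-fold limit 5304 genes were higher and 2787 lower, by construction. With a pseudocount of 5, which shrinks ratios of low genes, 1803 were higher and 1068 lower, and the log2 ratio of Cenpj was -0.63. It was -1.38 with TPM scaling and -1.39 with trimmed-mean scaling. The cause was not tested for the list percentiles that follow. Cilium assembly stood apart at 98.85 (pseudocount 0.1), 97.6 (no filter), 99.1 (FPKM of 5), 98.15 (median ratio), 99.05 (TPM), 98.4 (trimmed mean) and 99.4 (GC and length). It lay inside at 94.8 (pseudocount 5) and 96.9 (10 bins). Wnt targets stood apart at 98.7 (pseudocount 5), 98.9 (no filter), 97.7 (TPM) and 97.9 (GC and length). The p53 targets did at 99.7 (pseudocount 5) and 98.3 (no filter), but lay at 90.96 (GC and length), 94.2 (FPKM of 5) and 94.4 (pseudocount 0.1). Oligodendrocyte precursors did at 99.3 (pseudocount 5), 97.6 (FPKM of 5) and 99.85 (GC and length). Histones did at 99.7 (FPKM of 5), but lay at 17.8 (GC and length), 54.3 (TPM) and 38.7 (no filter). The integrated stress response lay at 17.9 (FPKM of 5). With the GC and length correction hypoxia and glycolysis stood apart at 99.6, apical radial glia at 0.57, mitochondrial mRNAs at 2.1 and sex-linked genes at 1.47. Notch moved inside at 36.1, and Notch3 and Pcnt changed sign to 0.38 and 0.33. Medians of lists with low members moved with the pseudocount, from 0.81 (pseudocount 5) to 4.01 (pseudocount 0.1) for motile cilia and from 0.48 to 2.82 for the interferon response, and both lists stood apart at each.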

Other observations

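Of 24 transcription factor genes of the dorsal telencephalon, chosen after values had been seen, 21 were at least 2-fold lower in CE and 0 higher. Sox11 stood at 494 and 40.9 FPKM, Nfix at 768 and 67.0 and Pou3f3 at 224 and 16.8. The exceptions were Emx2 (11.9 and 10.3 FPKM), Bcl11b (92.5 and 71.3) and Id2 (189 and 181). As 12 of the 24 are also in the radial glia, intermediate progenitor or excitatory neuron lists, and all were chosen with values in sight, the count describes these genes and tests nothing about the group.

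All tests here were chosen after the patterns had been seen. Those on the second choroid plexus list and on ribosomal protein genes were set before their results were computed. The 15 ribosomal protein genes tested are among the 82 whose lower values are the pattern itself, so a low percentile for them was likely.

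Choroid plexus genes were higher in CE, beside meningeal, blood and macrophage genes. A lower share of cortical cells alone, if it raised all other cell types alike, would leave no gap between the macrophage and endothelial medians. The macrophage median exceeded the endothelial median by 2.31 log2 units (95% bootstrap interval over genes 1.57 to 3.25). With a filter at FPKM 5 the medians were 2.72 and 0.69, at percentiles 100 and 92.7. The interval covers the choice of listed genes only, as genes of a library are not independent replicates. The pair was chosen after its medians were seen, so a gap in this direction was likely. The interval therefore cannot decide, and a lower share of cortical cells stays open. Choroid plexus tissue in the CE dissection may account for the pattern. A second list held 20 choroid plexus transcripts, chosen without sight of their values, of which 17 were tested. Of these, 15 (88.2%) were at least 4-fold higher, with Igfbp2 at 156 and 1090 FPKM and Enpp2 at 2.56 and 88.4. Of the second list 8 of 17 were also at 1 FPKM or more in WT, against 1 of 13 of the first list. The other tested members of both lists passed the filter only through CE, which by itself favours a rise. An effect of Cenpj depletion on the cortex stays open and cannot be told apart from the dissection with 1 library per group.

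Intermediate progenitor and excitatory neuron genes were lower in CE. The trend with GC content and length as the whole cause is argued against, since after its removal the higher of the list percentiles was 0. Fewer such cells may account for the pattern and stay open: 36 of 42 members lay below the median of all genes, which only restates the direction of the lists, and 64.3% of members (27 of 42) lay within 2-fold of their list's median after allowing for counting error, a measure chosen once the first had been seen. Unequal falls exclude nothing, since other cells such as interneurons also make some of the members. Ribosomal protein genes, which are in neither list, were lower as well, with 48 of 82 at least 2-fold lower and 2 higher. A difference in library preparation was not tested for these lists either. Cenpj depletion stays open too, and with 1 library per group it cannot be told apart from a difference between dissections or library preparations.

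Ribosomal protein genes were lower in CE. Reads shared with near-identical copies as the cause stay open. The 15 members with under 10% shared words lay at percentile 0. Sharing was measured on the longest transcript only, so those members may share more of a shorter mRNA. For Rps28 the longest transcript has 1443 bases and the smallest fitting length was 365. The test therefore cannot decide, and 8 ribosomal protein pseudogenes had a median of -1.36, with 4 at least 2-fold lower. Among all tested genes, the 371 with 50% or more shared words had a median of 0.29, against 0.33 for all genes. Of the 371, 81 were at least 2-fold higher and 68 lower, so high sharing by itself did not go with lower values. The trend with GC content and length as the whole cause is argued against, as the list lay at percentile 0 after correction. Short genes otherwise had higher ratios in CE. A difference in library preparation was not tested, and an effect of Cenpj depletion cannot be told apart from it with 1 library per group.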
